A study of Capra hircus with 12 samples.

How the data were processed

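The deposited table gives 1 value per gene and library under a column heading of TPM. Its library sums run from 904623 to 1127797 where that unit would give the same sum in each, so the signal values, as deposited, had been rescaled across libraries by steps the authors do not describe. Reads were quantified with kallisto 0.46.1 and compared with sleuth 0.30.0 per the submitters' processing notes, RNA was extracted with RNAiso Plus and sequenced on an Illumina HiSeq 4000 per the labels, and the authors name no genome build. The plan fixed before the files were seen allowed for read counts; the unit turned out to be a normalized one, so the limma branch of the plan was used. Read depth is unknown because a rescaled value does not carry it.

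Values were taken as log2(value + 1). Genes with a value of at least 1 in at least 2 libraries were tested, 16095 of 20326. Adding 1 shrinks the fold changes of genes with low values. Linear models with moderated variances and a mean-variance trend were fitted in limma 3.58.1 under R 4.3.3, with 1 group per stage of 4 libraries for the stage comparisons and 1 group per month of 2 libraries for the month comparisons. Male and female were compared with month as a block. P-values were adjusted by the Benjamini-Hochberg method, and a gene passed at adjusted p < 0.05. The p-values measure the spread between these samples; whether the same animals were sampled in different months is not given, and each month has 1 female and 1 male. The replicate number marks sex.

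Gene lists were fixed before the data were examined and tested with camera in limma at its preset correlation of 0.01 between genes, then again with the correlation estimated from the data. A list needed at least 5 measured genes. Member counts are given over all genes and adjusted over the list alone. The statement that a member rose or fell refers only to members that passed.

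Genes were named by a rule. Per stage comparison these were the 10 largest rises and 10 largest falls among the genes that passed. All 4 libraries of one stage had to lie above all 4 of the other. The mean over the libraries of both groups together had to reach 5, and the symbol could not be a LOC number. Month comparisons and sex used 5 each way. MKI67, SHH, LEF1, FGF5, BMP2, BMP4, LHX2 and PRLR are reported whatever their result; KRT15 was fixed as well and is not analysed here. List examples come from the members with the highest means among those that passed. Unless stated, the examples printed kept their call under every alternative and with any 1 library left out. All genes with LOC numbers lie outside the rule, as does KDM6A in the comparison of the sexes. Any other gene named outside it is said to be so. As submitted, 26 symbols had been turned into dates, so symbols were taken from the reference table by gene number, which matched 20294 genes and left 32. A total of 4260 genes carry LOC names and 70 were at 0 in all libraries.

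No 2 libraries had equal values, zeros included, in more than 1.55% of the tested genes, so none is a copy of another. Alternatives to each choice were quantile normalization, no expression filter, another added constant, the replicate number as a block, averaged months, an estimated correlation for the lists, a correction for trends shared by neighbouring genes and every library left out in turn. Lists were tested with a library left out in the stage comparisons only. Where a list is given a single pair of counts, the counts adjusted over the list alone were equal. In a check of the method, values without group differences were drawn from each gene's mean and spread and 200 genes were changed by a log2 fold of 1: 94% were recovered for telogen against catagen, 94.5% for male against female, 62.5% for May against March, 29.5% for the F test over months and 0% for the interaction of sex and stage, which recovered 92% at a log2 fold of 2. The search for unusual libraries covered 133 groups, namely library measures and genes named by size or fixed in advance in each stage of 4 libraries and genes named for sex in groups of 6.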

Results

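RNA was sequenced from secondary hair follicles, the skin appendages that grow cashmere, of goats (Capra hircus) aged 1.5 years. Anagen, the growth phase, was sampled in May and September, catagen, the regression phase, in November and December, and telogen, the resting phase, in February and March. Each of the 6 months had 1 female and 1 male library, 12 in all. Read depth is unknown. A mean of 19127 ± 302 (SD, n = 4) genes had a value above 0 in anagen, 19026 ± 275 in catagen and 19880 ± 299 in telogen. Ribosomal protein transcripts took 20.1 ± 2.16%, 23.9 ± 2.01% and 15.01 ± 2.32% of the signal in the 3 stages, and transcripts of the mitochondrial genome took 1.83 ± 0.413%, 2.99 ± 0.629% and 9.25 ± 3.18%, with 4.63% in the March male. The first principal component held 52.1% of the variance; telogen libraries scored 22.97 to 56.4 on it and the other 8 scored -35.7 to -6.82.

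**Figure D1:**
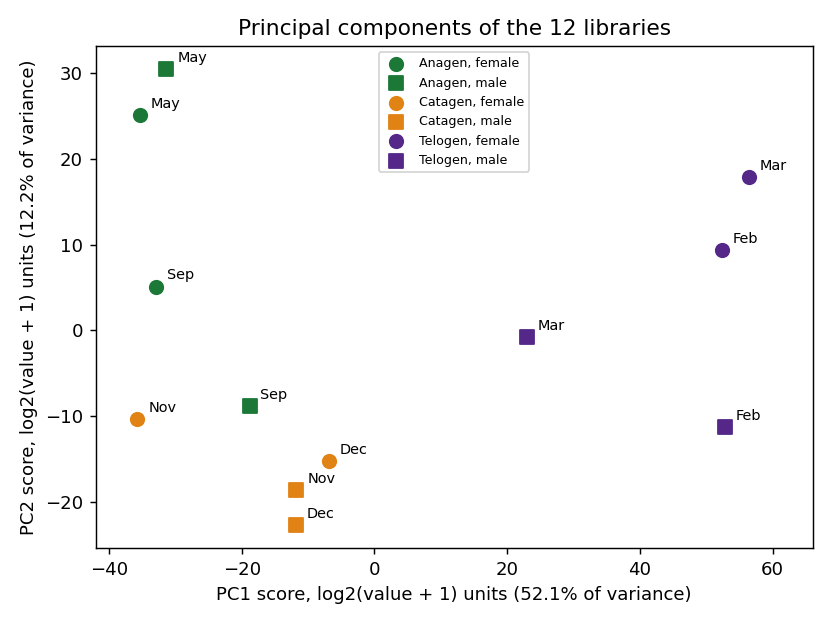
First and second principal components of the 12 libraries in units of log2(value + 1), with colour for stage, circles for females and squares for males, 1 point per library. The telogen libraries lie at 22.97 to 56.4 on the first axis, the March male nearest the other 2 stages.

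Among the months, February and May most often held the highest or lowest mean. The mean was highest in February for 2166 (41.2%) of the genes that differed among the 6 months and in May for 1519 (28.9%), followed by 552 in September, 471 in November, 381 in March and 170 in December. It was lowest in February for 2040 and in May for 1273. These are ranks of means of 2 libraries: March against February gave 1 gene, and the March male lay nearer the other stages on the first principal component than the other telogen libraries did (22.97 against 52.4 to 56.4). In total 5259 of 16095 genes (32.7%) passed the F test over months with 2 libraries in each. The number was 44 among the other 4 months when the 4 telogen libraries were left out, a choice made after the result was seen, and 2676 without the May female, 2634 without the May male, 3382 without the September female and 2344 without the February male.

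**Figure D2:**
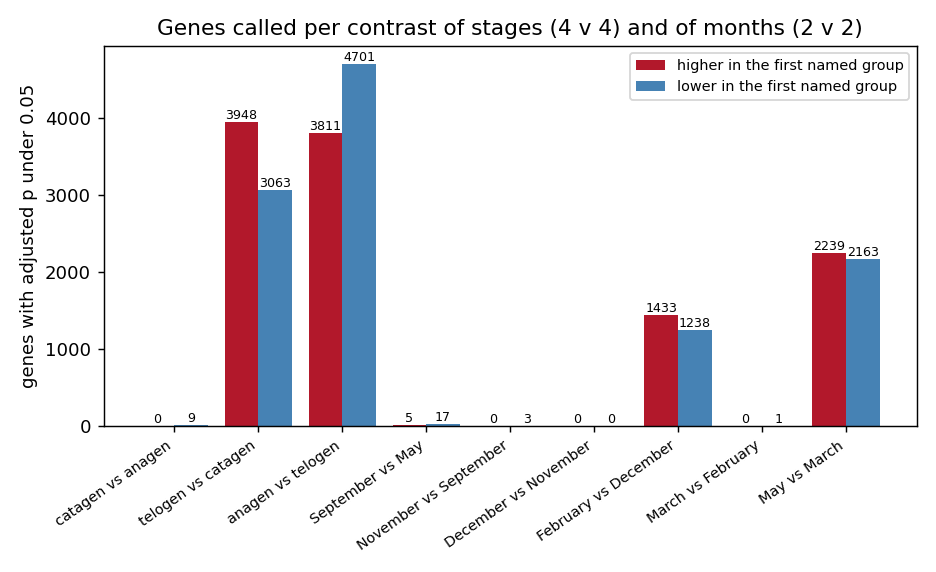
Number of genes higher (red bars) and lower (blue bars) in the first-named stage or month of each comparison at adjusted p < 0.05, stages with 4 libraries each and months with 2. Comparisons with telogen give 7011 and 8512 genes, and catagen against anagen gives 9.

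Catagen was compared with anagen to find what changes as hair growth ends. S100A7A (gene ID 102173556), an S100 calcium-binding protein of stratified epithelium, fell by 7.52 on the log2 scale (SE 0.523, adjusted p = 3.40e-05), from 276 ± 105 (SD, n = 4) to values of 0.91, 0.46, 0 and 0.41, and kept its call in 21 of 21 alternatives. KLK12 and KLK8, kallikrein-related serine proteases of the outer epidermis, fell by 0.95 (SE 0.127, adjusted p = 0.017; 107 ± 17.8 to 54.5 ± 8.12) and 1.24 (SE 0.185, adjusted p = 0.0323; 19.7 ± 2.60 to 7.92 ± 2.32). PLIN3, a coat protein of lipid droplets, fell by 0.90 (SE 0.134, adjusted p = 0.0323; 29.7 ± 3.77 to 15.6 ± 3.45). KLK12 lost its call without the May male, September female, December female or December male, and in 7 of 21 alternatives in all (adjusted p up to 0.162). KLK8 and PLIN3 lost theirs in 12 of 21 alternatives each, with any library left out except the November, February or March female (adjusted p up to 0.282 and 0.297). The other genes that fell, outside the naming rule, were LYPD2, CAPN14, TMEM266, LOC108633164 and LOC102191570. Not all of them kept their calls: without the September female only 3 genes passed in all, S100A7A among them. LOC102191570 went from 433 ± 163 to 4.28 ± 2.35 (SD, n = 4).

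No gene rose and 9 fell, 2519 of 16095 having an unadjusted p < 0.05 in limma; with month means averaged per stage 3 rose and 26 fell. The genes fixed in advance did not pass: SHH, the hedgehog ligand of growing follicles, changed by 0.37 (SE 0.137, adjusted p = 0.267), LEF1 by 0.23, BMP2 by 0.14, PRLR by 0.07, FGF5 by -0.03, BMP4 by -0.05, MKI67 by -0.06 and LHX2 by -0.11. Camera called 9 lists, each with adjusted p = 0.971 with an estimated correlation, and in none of them did a member pass over all genes. Cell division genes were higher (median log2 change 0.22, 31 of 36 positive, adjusted p = 2.96e-06, and adjusted p = 0.971 with an estimated correlation), as were ribosomal proteins (0.26), mitochondrial genome transcripts (0.68, 13 of 13 positive), smooth muscle (0.37), endothelium (0.20) and BMP and TGF-beta signalling (0.09). Skeletal muscle (-0.91, 13 lower adjusted over the list alone), epidermis (-0.34) and dermal fibroblast matrix (-0.26) were lower. The skeletal muscle genes of anagen were high in May, a median of 1.45 above catagen and telogen against 0.054 in September, and without both May libraries that call had adjusted p = 0.0421. For the 9 lists, 14 of 35 splits of the same 8 libraries gave as many list calls. Smooth muscle was not called without the May male (adjusted p = 0.169) or the November male (0.0647), and its direction turned when both May libraries were left out, which also ended the calls of ribosomal proteins (0.0624) and of BMP and TGF-beta signalling (0.0931). Endothelium lost its call without the September male or November male, fibroblast matrix without the September female, September male, November male or December female, and BMP and TGF-beta signalling without the May male, September male, November female or December female, with quantile normalization (0.055) and with the neighbourhood correction (0.106). The gene count was 4 without the May male, 3 without the September female, 3 without the December female, 4 without the December male, 5 without the February male and 5 without the March male.

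Telogen was compared with catagen to describe the resting follicle. The complex I subunit ND1, encoded in the mitochondrial genome, rose by 2.54 (SE 0.509, adjusted p = 0.00226), from 394 ± 97.7 to 2820 ± 1534 (SD, n = 4), with the March male at 547.9 and the other telogen libraries at 3268 to 3858. MMP7, a matrix metalloproteinase, rose by 1.90 (SE 0.304, adjusted p = 8.06e-04; 4.46 ± 1.39 to 21.0 ± 11.4), and SPRR4, a cornified envelope precursor, by 2.40 (SE 0.458, adjusted p = 0.0018; 45.9 to 304). RRP36 (gene ID 102172581), which takes part in processing of ribosomal RNA, fell by 2.35 (SE 0.0999, adjusted p = 6.74e-08; 25.8 ± 2.16 to 4.27 ± 0.629). MT4, a metallothionein of stratified epithelium, fell by 2.69 (SE 0.51, adjusted p = 0.00172; 1690 ± 855 to 306 ± 242), and RPL39, of the large ribosomal subunit, fell by 2.60 (SE 0.388, adjusted p = 5.90e-04; 893 ± 580 to 133 ± 46.6). S100A7A, almost absent in catagen, rose by 2.63 (SE 0.523, adjusted p = 0.00221). The remaining largest rises were ND4 (2.34), ND2 (2.29), ATP6 (2.12), ND6 (2.06), CYTB (1.91) and ND5 (1.84); the remaining falls were RRP7A (-2.85), RRP12 (-2.66), RRP1 (-2.55), RPLP2 (-2.30), S100A2 (-2.07), S-LZ (-1.99) and TOMM7 (-1.94).

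Keratins of the hair shaft fell, 5 of 8 with 0 higher (6 lower adjusted over the list alone; median log2 change -1.08, camera adjusted p = 0.0196, adjusted p = 0.851 with an estimated correlation). KRT35 fell by 1.07 (adjusted p = 0.0085; 529 ± 136 to 265 ± 116, SD, n = 4), KRT32 by 1.22, KRT84 by 1.29 and KRT40 by 1.32. Of 14 inner root sheath genes 8 fell and 1 rose (10 and 2 adjusted over the list alone; adjusted p = 0.036, and adjusted p = 0.851 with an estimated correlation). KRT74 of this sheath fell by 1.30 (203 to 92.7). KRT27 fell by 1.26 and KRT25 by 1.06, calls that were lost in 2 and 5 of 20 alternatives: KRT27 without the November female, KRT25 without the November female, November male, February female or March female, and either with quantile normalization. The inner root sheath list itself was not called without the November female (adjusted p = 0.0553), December female (0.0526) or March female (0.0523), and quantile normalization ended the calls of this list (0.152) and of hair shaft keratins (0.053). Among 18 regulators of the hair matrix 7 fell and 3 rose (8 and 3 adjusted over the list alone), with SELENBP1 at -1.42 and DLX3 at 0.70. KRTAP3-1, a keratin-associated protein, was higher by 1.20 (adjusted p = 0.0329), a call not made over its list alone and lost without the November female, November male, December male, February female or February male.

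Ribosomal protein and nuclear respiratory chain transcripts fell, and those of the mitochondrial genome rose. Of 79 ribosomal proteins 50 fell and 1 rose (54 and 2 adjusted over the list alone; median -0.75, adjusted p = 9.96e-14), among them RPLP1 (-1.34), RPS15A (-1.03) and RPL23 (-1.01); the list had adjusted p = 0.851 with an estimated correlation. Of 68 nuclear respiratory chain genes 42 fell and 1 rose (48 and 1 adjusted over the list alone; median -0.46, adjusted p = 1.67e-12), with ATP5A1 at -0.78, NDUFS5 at -0.59 and ATP5B at -0.55. Transcripts of the mitochondrial genome rose, 12 of 13 (13 adjusted over the list alone; median 1.84, adjusted p = 7.28e-05), COX1 by 1.77 (6697 ± 1507 to 24647 ± 10103, SD, n = 4) and COX3 by 1.40. The respiratory chain and mitochondrial lists likewise had adjusted p = 0.851 with an estimated correlation. Glycolysis genes fell, 6 of 20 with 0 higher (PGK1 -0.73, TPI1 -0.63, PGAM1 -0.46; adjusted p = 0.036, and adjusted p = 0.851 with an estimated correlation). The glycolysis call was lost without the November female (adjusted p = 0.0938), February male (0.0958) or March male (0.0523), and with quantile normalization (0.161). Of 20 cholesterol synthesis genes 8 fell and 0 rose (FDPS -0.97, INSIG1 -0.74, MSMO1 -0.59), a list that camera did not call (0.0609). The same libraries differed in their shares of ribosomal protein and mitochondrial signal, 23.9% and 2.99% in catagen against 15.01% and 9.25% in telogen.

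Cell division genes were split: 12 of 36 fell and 4 rose, in equal number adjusted over the list alone (median -0.19, adjusted p = 0.0196, and adjusted p = 0.878 with an estimated correlation). PCNA (-0.60), CCNB1 (-0.61), MCM7 (-0.56) and MCM3 (-0.56) fell, whereas MKI67, a marker of cycling cells, rose by 0.43 (adjusted p = 0.0161; 12.2 ± 2.16 to 16.7 ± 1.97, SD, n = 4). This list was not called without the December male (adjusted p = 0.0561) or February female (0.128), or with quantile normalization (0.0639). In Notch signalling 7 of 15 genes fell and 1 rose (NOTCH3 -0.87, JAG1 -0.59, NOTCH1 -0.58, RBPJ 0.44; adjusted p = 0.036, without the March male 0.0523, with quantile normalization 0.0639, and adjusted p = 0.851 with an estimated correlation). Of 44 Wnt signalling genes 12 fell and 5 rose (12 and 4 adjusted over the list alone; CTNNB1 -0.75, WNT11 -1.05), and of 31 BMP and TGF-beta signalling genes 10 fell and 7 rose (12 and 7 adjusted over the list alone; ID1 -0.92, ID3 -1.23, BAMBI -1.33, BMPR2 0.54). Of 22 bulge and stem cell genes 8 rose and 1 fell, with CD34 at 0.64 and LHX2, a transcription factor of follicle stem cells, at 0.62 (adjusted p = 0.0121; 32.0 to 50.2). Camera did not call the Wnt, BMP and TGF-beta and bulge lists (adjusted p = 0.164, 0.316 and 0.138). PRLR, the prolactin receptor, rose by 0.80 (SE 0.165, adjusted p = 0.00272; 56.0 ± 7.23 to 99.3 ± 23.1, SD, n = 4). LEF1 (0.21), SHH (0.21), BMP4 (-0.26), BMP2 (-0.43) and FGF5 (-0.52) did not pass, with adjusted p = 0.235, 0.235, 0.0638, 0.0535 and 0.23.

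Clock genes rose, 9 of 19 against 2 that fell, with RORA at 0.70, BHLHE40 at 1.01, CIART at 0.91 and NFIL3 at -0.52. Nerve and Schwann cell genes rose, 7 of 12 against 1 (8 and 1 adjusted over the list alone; PMP22 0.94, EGR2 0.63), as did T and B cell genes, 5 of 16 against 0 (GZMA 1.07, CD3D 0.68), and myeloid genes, 5 of 14 against 1 (LAPTM5 1.20, TYROBP 0.55). Apoptosis genes went either way, 8 up and 4 down of 24 (10 and 4 adjusted over the list alone; FAS 0.64, BCL2 0.75), and so did immediate early and stress genes, 6 up and 4 down of 25 (JUN -0.71, HSPD1 -0.74). Of 15 melanocyte genes 3 rose and 2 fell (median 0.42, 12 positive), and EDNRB, an endothelin receptor, fell by 1.42 against that median. PPARG rose by 1.16, MX2 by 1.29 and KLK5 by 1.00. Camera called none of these lists. In all 3948 genes were higher and 3063 lower in telogen, 43.6% of those tested, and 803 changed at least 2-fold. With quantile normalization the split was 3145 higher and 3183 lower, and without a filter 5558 higher and 3045 lower. As many list calls as here arose in 23 of 35 splits of the same 8 libraries.

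**Figure D3:**
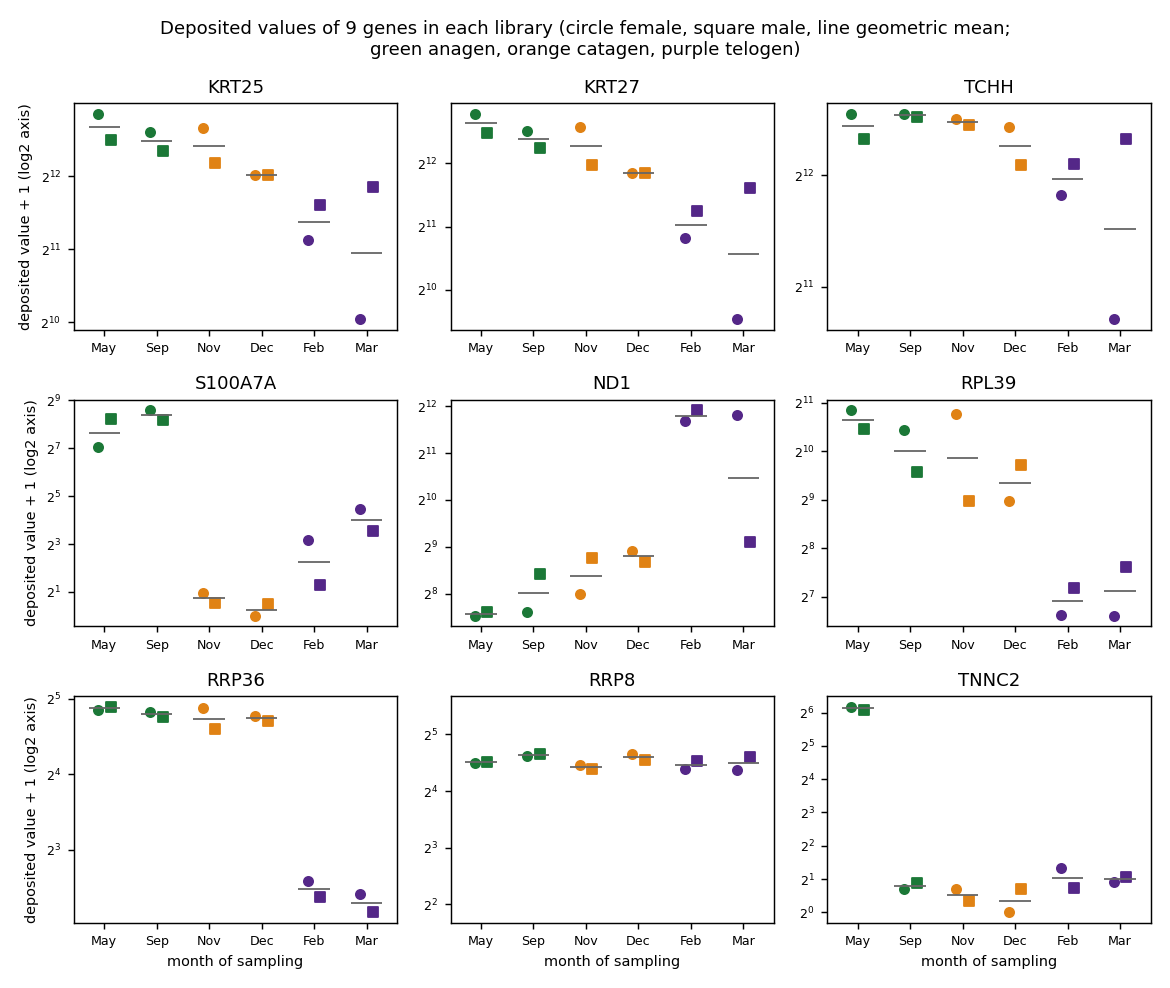
Deposited value + 1 of 9 genes by month on a log2 axis, circles for females and squares for males, 1 point per library and a line through the geometric means of 2. RRP36 is at 23.2 to 28.8 in anagen and catagen and at 3.5 to 5.03 in telogen, and TNNC2 is at 71.4 and 66.97 in May.

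Anagen was compared with telogen to describe the return of growth. Inner root sheath and hair shaft keratins were higher in anagen: KRT27 by 1.71, KRT25 by 1.42, KRT32 by 1.47, KRT35 by 1.09 and KRT84 by 1.09. RPL39, of the large ribosomal subunit, was higher by 3.32 (SE 0.388), S100A7A by 4.89 (SE 0.523, adjusted p = 1.11e-04, 4 libraries per stage) and RRP36 by 2.45 (SE 0.0999, adjusted p = 4.01e-08). SHH was lower in anagen by 0.58 (SE 0.137, adjusted p = 0.00361; 3.45 ± 0.653 against 5.64 ± 0.842, SD, n = 4), and PRLR by 0.86. MUCL1, a small secreted mucin-like protein, was lower by 4.43 (SE 1.07, adjusted p = 0.00415) and lost its call only without both May libraries (0.0711). Other large rises were S100A2 (3.0), MT4 (2.98), RPLP2 (2.94), RRP7A (2.76), RRP12 (2.74), RRP1 (2.65) and COPS9 (2.39), and other large falls were ND2 (-3.37), ND1 (-3.34), ND4 (-3.10), ATP6 (-2.99), ND6 (-2.57), CYTB (-2.54), ND5 (-2.52), COX1 (-2.44) and CDR1 (-2.29).

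Hair shaft keratins were higher in 7 of 8 with 0 lower (adjusted p = 0.00809) and inner root sheath genes in 9 of 14 with 2 lower (10 and 2 adjusted over the list alone; adjusted p = 0.0268), each with adjusted p = 0.9205 with an estimated correlation. Ribosomal proteins were higher in 36 and lower in 5 (RPLP1 1.27, RPL35 1.11), respiratory chain genes higher in 41 and lower in 3 (ATP5A1 0.97, ATP5B 0.65), glycolysis genes higher in 10 and lower in 1 (TPI1 0.55, PGAM1 0.43), and all 13 mitochondrial transcripts were lower (median -2.52). With skeletal muscle, 6 higher and 1 lower of 20, these were the 7 lists camera called, and the other 5 too had adjusted p = 0.9205 with an estimated correlation. The skeletal muscle call was lost without the May female (adjusted p = 0.102), May male (0.126) or March male (0.081), without both May libraries (0.5385) and with the neighbourhood correction (0.0502). The glycolysis call was lost without the September male (adjusted p = 0.0714), February male (0.0876) or March male (0.0706) and with quantile normalization (0.102). Among lists not called, bulge and stem cell genes were lower in 13 and higher in 2 (14 and 2 adjusted over the list alone; SOX9 -0.57), clock genes lower in 10 and higher in 3 (BHLHE40 -0.89, RORA -0.70, NFIL3 0.62), and Wnt genes higher in 14 and lower in 7 (14 and 6 adjusted over the list alone; CTNNB1 0.98, APCDD1 0.59). Cholesterol synthesis genes were higher in 8 and lower in 3 (INSIG1 1.32, FDPS 1.22), nerve and Schwann cell genes lower in 7 and higher in 1 (PMP22 -1.29), and KRTAP3-1 was lower by 1.82. Cell division genes were higher in 8 and lower in 8 (MCM7 0.58).

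LEF1, a Wnt transcription factor, was lower in anagen by 0.44 (adjusted p = 0.0174), LHX2 by 0.51 (0.0240) and MKI67 by 0.37 (0.0248), and BMP4 was higher by 0.30 (0.0283); BMP2 (0.30, adjusted p = 0.158) and FGF5 (0.55, 0.185) did not pass. LEF1 lost its call without the May male, February female or February male, LHX2 without the September female, September male, February female or March female, and MKI67 without the September female, September male, February male or March female (adjusted p up to 0.175, 0.0728 and 0.0722). BMP4 lost its call without the May male, September female, February female or March female (adjusted p up to 0.0797). Of all genes 3811 were higher and 4701 lower in anagen, 52.9%, with 1286 changed at least 2-fold; without a filter the split was 3778 higher and 6102 lower. As many list calls as here arose in 25 of 35 splits of the same 8 libraries.

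September and May, both in anagen, differed in muscle genes. TNNC2, a troponin of fast skeletal muscle, fell by 5.33 (SE 0.265, adjusted p = 1.55e-05), from 71.4 and 66.97 in the 2 May libraries to 0.64 and 0.85, and MYLPF, a myosin light chain, MYL1, ACTA1 and TNNT3 changed by -5.14, -4.01, -3.95 and -3.56. DES, an intermediate filament of muscle, rose by 2.06 (SE 0.227, adjusted p = 0.00603), from 23.59 and 17.72 to 88.58 and 88.68, with ACADSB at 1.45 and ACTA2, actin of smooth muscle, at 1.32. Skeletal muscle genes fell, 11 of 20 (15 lower and 1 higher adjusted over the list alone; median -1.45, adjusted p = 2.74e-28, and adjusted p = 0.00395 with an estimated correlation), while smooth muscle genes rose, 1 of 14 over all genes and 10 adjusted over the list alone (median 0.84, adjusted p = 5.29e-12, and adjusted p = 0.23 with an estimated correlation). In all 5 genes rose and 17 fell, and 5 rose and 7 fell with 0.1 added in place of 1. Camera called 11 lists. Besides muscle, ribosomal proteins (median 0.32, a direction that turned with quantile normalization), respiratory chain (0.10), myeloid (0.42), T and B cell (0.21), immediate early and stress (0.25) and cell division genes (0.12) were higher, and epidermis (-0.35), interferon response (-0.26, lost with quantile normalization) and bulge genes (-0.18) lower. These 9 had adjusted p = 0.23 to 0.783 with an estimated correlation; adjusted over the list alone 4 myeloid and 3 respiratory chain genes rose, and over all genes none of their members passed. The gene count was 8 without the May male, 12 without the September female and 11 without the September male. DES and ACTA2 lost their calls without any of these 3 libraries, ACADSB without the May female, May male or September male, and TNNT3 without the May male (adjusted p = 0.0542); MYL1 lost its call with 0.1 added (0.13).

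Between September and November S100A7A fell by 7.65 (SE 0.566, adjusted p = 0.00164, 2 libraries per month), a call lost without the September female (0.0501). LOC108633164 and LOC102168428, outside the naming rule, also fell, and no gene rose. In limma 299 of 16095 had an unadjusted p < 0.05, a smaller share than the 0.05 that tests without any difference would give. The count was 0 without the September female, 1 without the February female or February male and 5 without the March male. Camera called 7 lists: Notch signalling, endothelium, ribosomal proteins and mitochondrial transcripts higher, and fibroblast matrix, myeloid (median -0.34, 2 lower adjusted over the list alone) and T and B cell genes lower. They had adjusted p = 0.457 to 0.965 with an estimated correlation.

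December against November gave 0 genes in limma, with 588 of 16095 at an unadjusted p < 0.05. This is a smaller share than the 0.05 that tests without any difference would give. The count was 3 without the December female and 1 without the December male. Cell division genes were higher as a list and epidermis (median -0.33) and smooth muscle (-0.39) lower, with adjusted p = 0.352 for epidermis and 0.986 for the other 2 with an estimated correlation.

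February was compared with December, the step from catagen to telogen. RRP36 changed by -2.26, RRP7A by -2.94 (SE 0.22, adjusted p = 3.57e-04, 2 libraries per month), RRP12 by -2.81 (adjusted p = 3.77e-05) and RRP1 by -2.58, and each kept its call in 18 of 18 alternatives. ND1 rose by 3.0, SPRR4 by 2.77, ND4 by 2.71 and ND2 by 2.63, and RPL39 fell by 2.44; these and LUZP6 lost their calls without any 1 of the December or February libraries (adjusted p up to 0.152), SPRR4 also without either September library. LUZP6 rose by 3.94; it is listed at 0 in 9 libraries, at 11.04 and 18.43 in February and at 16.23 and 0 in March. Mitochondrial genome transcripts rose in 11 of 13 (12 adjusted over the list alone; median 2.12). Ribosomal proteins fell in 17 (19 adjusted over the list alone), nuclear respiratory chain genes in 19 (26, with 1 higher), cell division genes in 6 with 1 higher (10 and 1), Notch genes in 5 (6, with 1 higher) and cholesterol synthesis and glycolysis genes in 5 each. These 7 lists had adjusted p = 0.894 with an estimated correlation. With quantile normalization the Notch (adjusted p = 0.0611) and glycolysis (0.0846) calls were lost. In all 1433 genes rose and 1238 fell, a share of 53.65% higher that became 38.66% with the neighbourhood correction, chosen after the result was seen. The count of 2671 became 1544 without the May female, 1544 without the May male, 1752 without the September female, 1750 without the September male, 42 without the December female, 19 without the December male, 970 without the February female, 22 without the February male, 4468 without the March female and 4393 without the March male.

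March against February gave 1 gene in limma, LOC106503204, which fell by 1.60 from 173 and 164.3 to 56.7 and 53.14. Of 16095 genes 636 had an unadjusted p < 0.05, a smaller share than the 0.05 that tests without any difference would give. The count was 0 without the March male or any 1 library of September, November, December or February, 2 without the May female or May male and 12 without the March female. As lists, mitochondrial genome transcripts (median -0.90), smooth muscle (-0.30) and hair matrix regulators (-0.23) were lower, and interferon response (0.26) and cholesterol synthesis (0.15) higher; the 5 had adjusted p = 0.859 with an estimated correlation. The mitochondrial share of signal was 11.8% in the March female, above the 9.88% and 10.67% of February, and 4.63% in the March male.

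May against March brought a rise in skeletal muscle genes: TNNC2 by 5.14, MYLPF by 5.01, ACTA1 by 4.39, TNNI2 by 3.88 and MYL1 by 3.73. MUCL1 fell by 5.30 and is listed at 0 in both May libraries against 34.57 and 42.69 in March. ND2, ND1, ATP6 and ND4 changed by -3.37, -2.89, -2.75 and -2.70, calls lost without the May female or May male. Skeletal muscle rose in 15 of 20 with 0 lower (16 adjusted over the list alone; adjusted p = 0.045 with an estimated correlation). Hair shaft keratins (3 higher), inner root sheath (4 higher, 1 lower), ribosomal proteins (22 and 5) and respiratory chain genes (20 and 6) rose and 12 mitochondrial transcripts fell; adjusted over the list alone the higher counts were 3, 7, 23 and 29 and the lower mitochondrial count 13. These 5 lists had adjusted p = 0.942 to 0.957 with an estimated correlation. In all 2239 genes rose and 2163 fell, with 2 libraries per month. The count of 4402 became 225 without the May female, 382 without the May male and 1432 without the March female.

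Males and females were compared within months. LOC108634721 was higher in males by 5.64 (55.5 ± 7.25 against 0.128, SD, n = 6), LOC108634550 by 5.08 (37.4 ± 4.64 against 0.127), LOC108634720 by 4.64 and LOC108634619 by 4.49, in 6 of 6 months. EIF2S3, a translation initiation factor subunit carried on the X chromosome of mammals, was lower by 0.64 (SE 0.0706, adjusted p = 0.0207; 65.6 ± 6.83 against 103 ± 13.8, SD, n = 6). ZFX, an X-linked zinc finger protein, was lower by 0.55 (SE 0.0672, adjusted p = 0.0422; 23.5 ± 2.06 against 34.8 ± 2.84). EIF2S3 lost its call in 13 of 19 alternatives (adjusted p up to 0.149) and ZFX in 17 of 19 (up to 0.253), EIF2S3 with any library left out except those of March. KDM6A, an X-linked histone demethylase, was lower by 0.66 in 6 of 6 months and did not pass (adjusted p = 0.123). In all 7 genes were higher in males and 2 lower, with 1185 at an unadjusted p < 0.05.

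The difference between males and females varied by stage in limma for 1 gene, LOC102173355 (adjusted p = 0.0241), listed at 0 in 10 libraries, at 4.42 in the February male and at 3.76 in the March male. A total of 1494 genes had an unadjusted p < 0.05 in limma. The count was 0 without the September female, September male, December female, December male, February female or March female, 2 without the May male, 3 without the February male and 4 without the November female or November male. LOC102173355 lost its call to other genes without the May female (1 gene), March male (1) or February male (3) and with 0.1 added in place of 1 (1).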

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

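The tests of neighbouring genes, of other cell types, of differences inside a month, of other ribosome biogenesis genes and of RRP symbols were chosen only after the result was seen.

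In a search of 133 groups for a library that stood alone, 19 groups had one. Chance alone would give about 1 in 20 among independent groups. These groups share libraries, and genes such as the mitochondrial transcripts move together. The 19 can therefore not be set against that rate as a test. In anagen the September male had ND1 at 339.5 against 183 to 194 in the other 3 libraries, RPLP2 at 879.7 against 1485 to 1653 and TOMM7 at 200.1 against 298 to 320. In catagen the December female had ribosomal proteins at 20.94% of signal against 24.7 to 25.1% and MKI67 at 15.41 against 10.7 to 11.4. The November female had PLIN3 at 20.75 against 13.6 to 14.2, ATP6 at 1007 against 1555 to 1690 and RRP1 at 31.05 against 27.75 to 27.85. In telogen the February female had PLIN3 at 18.56 against 21.5 to 22.0.

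The March male differed from the other 3 telogen libraries in 10 groups, most of them transcripts of the mitochondrial genome and so not independent. Its score on the first principal component was 22.97 against 52.4 to 56.4. Its mitochondrial transcripts were lower: ND1 547.9 against 3268 to 3858, ND4 694.1 against 2956 to 3586, ND2 454.4 against 1955 to 2209, ATP6 2060 against 8268 to 10266, ND6 330.1 against 1431 to 1692, CYTB 1446 against 5378 to 6727, ND5 402.7 against 1346 to 1636 and COX1 9813 against 26708 to 31455. RRP7A was at 1.94 against 0.94 to 1.08. The count of genes between telogen and catagen ran from 5257 to 7545 with any 1 library left out. The interaction of sex and stage gave LOC102173355 alone, at an adjusted p of 0.02413.

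The telogen libraries lay apart from the other 8, and any batch shared by the February and March libraries, of which the labels say nothing, cannot be told apart from stage. A trend shared by neighbouring genes is argued against as the whole cause: with it removed, 5509 of 7011 genes (78.6%) kept their call in telogen against catagen. The base composition of a gene's own transcript was not tested by this. A lower share of follicle cells stays open as a cause. Medians of lists for other cell types differed by 0.64 from lowest to highest, against a median middle spread of 0.51 within a list. They were -0.08 for smooth muscle (quartiles -0.38 and 0.13) and 0.56 for nerve (0.33 and 0.72), the extremes of 13 lists. Other cell types need not change in equal measure, so this range cannot decide. Of the 13 medians 11 lay above 0. The median over all tested genes was also above 0, at 0.07, so this count cannot decide either. Whether a library property that also varies inside a month contributes stays open: across genes the male minus female difference correlated with telogen minus anagen at r = 0.461 in November and -0.0844 in December. A change in the follicle itself was not tested by any of these, and transcript length was not examined.

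Genes with RRP symbols were low in all 4 telogen libraries, the March male among them, and took 5 of the 6 smallest p-values. Their median change of -2.16 was -2.04 after a trend shared by neighbouring genes was removed. This argues only against a trend shared with neighbours, since a cause that acted on single genes would be left in place. A fall of that size in ribosome biogenesis as a whole is argued against. The 73 other genes of that process had a median change of -0.24 (quartiles -0.54 and 0.008). This lay below the median of 0.07 over all tested genes, so a smaller fall of the process is not argued against. A processing step that acted on genes by their names could have touched them: 7 of 8 were lower by at least 1 on the log2 scale, RRP8 was not (-0.04), and the files cannot settle it. Sequences or read alignments would be needed to go further.

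Among 35 splits of the 8 libraries of a pair of stages, 2 gave at least the 9 genes of catagen against anagen, and the highest other split, the May pair with the September and November females against the rest, gave 943, so structure within these libraries exceeds that comparison. Only the true split, 1 of 35, reached the gene counts of telogen against catagen (next 2) and of anagen against telogen (next 0). Likewise 1 of 32 exchanges within months reached that of male against female (next 0). A random grouping of single libraries is argued against there. The splits of stages treat the libraries of a month as independent, so they cannot decide between stage, month and batch. For lists called by camera, 14, 23 and 25 of 35 splits gave as many in catagen against anagen, telogen against catagen and anagen against telogen, with highest other counts of 14, 18 and 22. The list calls may therefore arise from differences between any groups of these libraries, as the loss of all of them with an estimated correlation, 0 in each stage comparison, also allows.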

How the results depend on the processing

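The alternatives fixed in advance were joined by a neighbourhood correction, the fit without the 4 telogen libraries and the fit without the 2 May libraries, all 3 chosen only after the results were seen. Stage is spread over 2 months of 1 female and 1 male each, so month, stage and any batch by month are joined, and with 2 libraries per month a single library decides many calls. The unit is rescaled, animals are not identified, and genes that share reads with near-identical copies are uncertain. The replicate number marks sex and was not taken to pair animals: across 15 pairs of months the correlations of the within-month differences ran from -0.255 to 0.442, with a median of 0.114, 9 over 0.1, 12 over 0 and 3 not. With the replicate number as a block the counts were 9 for catagen against anagen, 7074 for telogen against catagen, 8624 for anagen against telogen and 1 for November against September, and the glycolysis list lost its call for February against December (adjusted p = 0.0547).

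Without a filter, sex by stage gave 4 genes. With 0.1 added in place of 1, September against May gave 12 and November against September 5. With month means averaged per stage, catagen against anagen gave 29, 3 higher and 26 lower. With the neighbourhood correction catagen against anagen gave 4 and March against February 0, and CCNA2, lower in anagen than telogen by 0.36, changed sign to 0.024. Without the 4 telogen libraries catagen against anagen gave 4 and the months 44. Without the 2 May libraries catagen against anagen gave 4, February against December 1551, March against February 2 and the months 2712. Under quantile normalization 3 lists were called for telogen against catagen. With an estimated correlation 0 lists were called for catagen against anagen, telogen against catagen, anagen against telogen, November against September, December against November, February against December and March against February, 1 for September against May and 1 for May against March.

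With any 1 library left out, catagen against anagen ran from 3 (September female) to 13 (March female), September against May from 8 (May male) to 33 (March female), November against September from 0 (September female) to 5 (March male), December against November from 0 (May female) to 3 (December female), February against December from 19 (December male) to 4468 (March female), March against February from 0 (September female) to 12 (March female), May against March from 225 (May female) to 5977 (March male), the months from 2344 (February male) to 7221 (March male) and sex by stage from 0 (September female) to 4 (November female). Telogen against catagen ran from 5257 to 7545, anagen against telogen from 7337 to 8668 and male against female from 6 to 8. Over 99 results for named genes the alternatives gave 1923 values, of which 1782 kept the result, 126 were weaker, 5 stronger and 0 reversed, and 10 changed sign without a call. Over 836 results for list examples there were 15817 values, of which 13751 kept the result, 1657 were weaker, 13 stronger and 1 reversed, and 395 changed sign without a call.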

Other observations

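The genes of the next 2 paragraphs were singled out only after their values were seen, and so were the tests of the muscle genes after them.

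A pair of genes without symbols had values that did not follow the stages, for a reason that was not tested. LOC102176710 was at 54.75 to 97.3 from September to December and at 0.67 to 2.2 in May, February and March, and LOC102168680, next to HBM, a haemoglobin gene, was at 28.5 to 95.4 and 0.31 to 1.54 in the same libraries. They were thus low in May and high in September although anagen holds both months. LOC102172558, between CNGB1 and TEPP, was at 188.5 to 478.8 in the 4 telogen libraries and at 0 to 16.0 in the other 8. LOC102189079 was at 5.34 to 9.78 in telogen and at 0 to 0.92 elsewhere, and its neighbour LOC102189358 at 5.92 to 7.52 in telogen. LOC102169411 and LOC102168380, also neighbours, peaked in September at 2550 and 3568 and at 2771 and 2539.

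Some genes beside KRTAP3-1, in the region of keratin-associated proteins, had their highest values in February. This was so in both February libraries for 11 of 27 tested genes within 15 positions on either side, and for 940 of 16095 among all tested genes, where the first count includes the genes for which the region was singled out. The median change of the 27 genes was 0.23 from December to February, with 16 positive, and -0.99 from February to March. LOC102170546, next to KRT40, was at 2570 and 2770 in February and at 553 to 1090 in other months, and LOC100861179 at 103 and 94.7 against 14.8 to 39.2. Beside MUCL1, LOC102184404 was at 54.2 and 335 in May, at 2987 to 12821 from September to December and at 20578, 13692, 23761 and 5847 in February and March.

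Skeletal muscle genes were high in both May libraries. In 15 of 20 such genes both May values lay above those of the other 10 libraries, which describes the pattern and favours no source of it. Muscle genes expressed by the follicle throughout anagen are argued against, as September, also anagen, lay 0.054 above catagen and telogen while May lay 1.45 above. Muscle left on the May samples and a change of the follicle in May alone cannot be told apart, as no test here separates them. Of 14 smooth muscle genes 6 had both May values below the rest.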
